A study of Mus musculus with 4 samples.

How the data were processed

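RNA of C2C12 mouse myoblasts infected with control retrovirus (2 arrays) or SYT-SSX2 retrovirus (2 arrays) was hybridised to Affymetrix arrays, 1 biotin-labelled sample per array. The groups and replicate numbers were taken from the sample titles. The labels state 2 independent experiments but do not say that a replicate number marks an experiment, so the main comparison has no pairing.

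The values used were those of the deposited series matrix, 1 column per array and 35557 probe sets, with 0 columns left unused. They are on the log2 scale, as the authors deposited them, and range from 2.69 to 14.9. Per the submitters' processing notes, RMA, GCOS and Affymetrix Expression Console were used, without versions and without the part each played. Scanner files, detection calls, the array's scan date and a genome build are not given in the sources used here, so no background call or batch could be added and no coordinates are given. RMA values near the array's background compress folds, and the array holds no spike that would show a change in total RNA per cell.

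Gene names came from the platform table given with the values. It paired 21789 probe sets with 1 gene symbol and 1621 with several, and 12147 probe sets are unnamed here. Of the 21789, 21698 had a gene number in a RefSeq gene table (assembly GRCm38.p6), and 0 symbols needed an update. That table was used only for symbols, gene types, the order and overlap of neighbouring genes, and the chromosome of keratin genes. Probe sets with several symbols were named for no gene. For the 999 genes with more than 1 probe set, the one with the highest mean over the 4 arrays was used, which left 19938 genes. The values of 701 probe sets were identical to those of another probe set, which held for 0 of the tested genes.

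Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term, no filter on level), with Benjamini-Hochberg adjustment over 19938 genes. A gene was called at an adjusted p under 0.05. The fit had 2 residual degrees of freedom per gene, 8.306 prior degrees of freedom and a prior SD of 0.125 (log2). Differences are fusion minus vector, SE is limma's moderated standard error, and a fold is 2 to the power of the log2 difference.

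The 42 gene lists, the comparison, the thresholds and the rule for named genes were fixed before the data were examined. The lists were written from general knowledge of myoblasts, of the fusion protein and of infection, and older symbols in them were matched to current ones. They were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over the 42 lists. Some genes are in more than 1 list, such as Des, Krt14 and Lif. Named genes were the 12 largest rises and 12 largest falls among called genes with the same sign in both same-numbered pairs, leaving out unnamed or predicted loci, chemosensory receptors and small RNAs. To these were added up to 4 called members of each list with the largest difference (up to 2 as values where none was called) and genes fixed by name, of which H19, Ephb2, Cdkn1a and Gapdh, among others, had no probe set of their own and were not analysed here.

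The procedure was tested on 20 simulated data sets of 19938 genes and 2 arrays per group, each with 200 changed genes. Gene means were those observed, and variances were drawn from limma's fitted prior, with normal noise. Genes changed by 0.5, 1 and 2 (log2) were recovered in 15.5%, 97.2% and 100% of cases, 4.88% of calls were false, and the median number of calls with no gene changed was 0. A list shifted by 0.3 (log2) was called in 100% of data sets. The recovery holds for that number of changed genes: with more of them, as in the real data, the adjusted threshold is less strict. The list test was simulated without correlation between genes. Since the simulated variances follow limma's own model, a share of false calls near the threshold was built in. It does not measure that share in the real data.

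The alternatives were filters on dim genes, all probe sets or the mean of a gene's probe sets, a variance trend, robust estimation, 3 further normalizations, the replicate number as a block, other thresholds, other list tests, and each array left out in turn. In the last case the group with a lone array is assumed to vary like the other. Groups of 2 are too small for a test of outlying arrays or of other splits of the samples.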

Results

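Gene expression was measured in C2C12 cells, a mouse myoblast line that can be induced to form muscle fibres, after infection with a retrovirus. The virus carried either the empty pOZ vector or SYT-SSX2, the fusion of a chromatin remodelling subunit (SYT, also called SS18) with an SSX protein that is found in synovial sarcoma. Total RNA was taken 48 h after an infection of 6 h in medium with 10% serum, in 2 independent experiments. Each group therefore had 2 Affymetrix arrays, 4 in all, and this number limits the precision of every value below. The median level of the arrays was 6.04 and 6.13 on the log2 scale in the vector group and 6.09 and 6.11 in the fusion group. Across genes, which are not independent replicates, the arrays of one group correlated at Pearson's r = 0.995 for both groups, and arrays of different groups at 0.977 to 0.9795. The median absolute difference between the arrays of a group was 0.129 on the log2 scale for the vector and 0.118 for the fusion. Olfactory receptor genes, most of which serve in sensory neurons, were taken as a measure of the background: 1027 of them had a median level of 4.11 and a 95th percentile of 5.52.

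The single comparison was of fusion against vector cultures, and it asked which genes differ once SYT-SSX2 is introduced. The introduced gene was looked at first. The probe set of mouse Ss18 (10457598) read 8.45 ± 0.061 (SD, n = 2) in the vector arrays and 8.63 ± 0.159 (SD, n = 2) in the fusion arrays. Its log2 difference of 0.17 (SE 0.124) did not pass limma's test, with an adjusted p of 0.459. The 6 mouse Ssx probe sets, for Ssx9, Ssxa1, Ssxb2, Ssxb3, Ssxb5 and Ssxb10, had group means from 3.48 to 4.22, at background. By limma, 0 of these 7 probe sets passed, and 0 had an unadjusted p under 0.05. Whether these probe sets read the introduced transcript is not known from the files, so they neither bear out nor contradict the labels.

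The gene with the largest rise was Akr1c18, an enzyme that inactivates progesterone, and the gene with the largest fall was Aspn, which encodes the matrix proteoglycan asporin. Akr1c18 (probe set 10407435) went from 4.13 ± 0.124 to 11.54 ± 0.206 (SD, n = 2 each), or 169.8-fold (log2 7.41, SE 0.135, adjusted p = 9.04e-10). Aspn (probe set 10405047) went from 10.31 ± 0.259 to 4.58 ± 0.145 (SD, n = 2 each), or 52.9-fold lower (log2 -5.73, SE 0.145, adjusted p = 1.38e-08). Of 19938 genes tested, 2522 differed at an adjusted p under 0.05, of which 1207 rose and 1315 fell. At least 2-fold changes were seen in 585 of them, 256 higher and 329 lower, and 56 rose and 55 fell at least 4-fold. The groups did not overlap in any of the 2522, so that all 2522 necessarily had the same sign in both same-numbered pairs of arrays. The smallest called difference was 0.384 on the log2 scale. Of the 256 genes that rose at least 2-fold, 67 had a vector mean under the 95th percentile of the olfactory receptors, and 55 of the 329 that fell had a fusion mean under it, so that the fold of these genes, and their rank by fold, depends on the background. They include Akr1c18, Krt6a, Cbln1, Krt5, Nts, Krt6b and Ehf of the 12 largest rises and Aspn and Dcn of the 12 largest falls. Among the genes named from the lists they include Acan, Kdr and Nrarp, which rose, and Phex and Ifit1, which fell. Among the olfactory receptors themselves, 4 rose and 6 fell. When all 35557 probe sets entered the fit, unnamed ones included, 1098 probe sets passed, among them those of 826 of the 2522 genes.

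**Figure D1:**
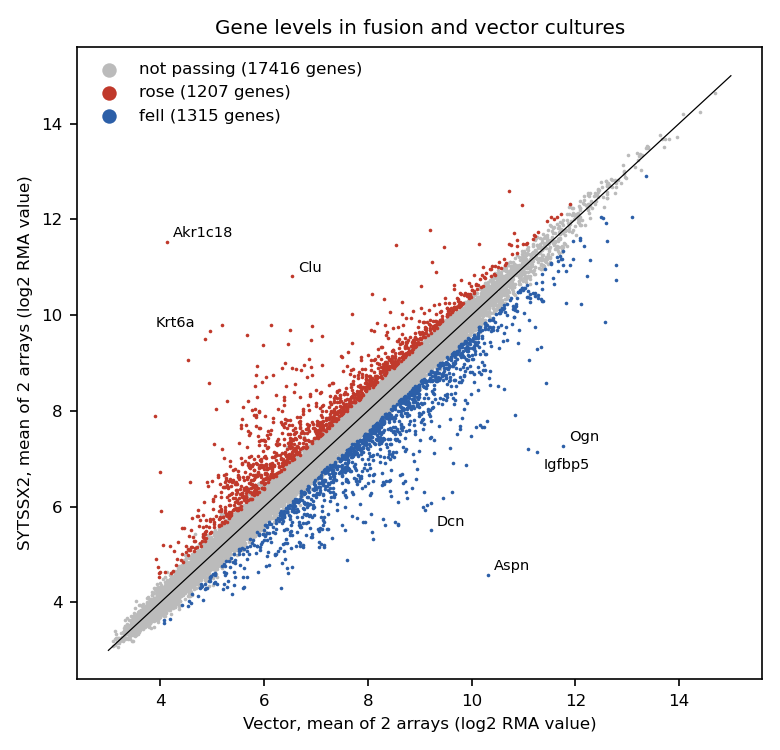
Mean log2 RMA value of each of 19938 genes over the 2 fusion arrays (y axis) against that over the 2 vector arrays (x axis), with the line of equal levels. Each point is a gene. The 1207 genes that rose are red and the 1315 that fell are blue, and Akr1c18 and Aspn lie farthest from the line.

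The 12 largest rises held 3 keratin genes, 2 neuropeptide precursors and 3 transcription factor genes. From vector levels in the background range, Krt6a rose 26.2-fold (log2 4.71, SE 0.128), Krt5 rose 24.4-fold (log2 4.61, SE 0.16) and Krt6b rose 15.8-fold (log2 3.99, SE 0.222). These are type II keratins of stratified epithelia, and Krt6a and Krt6b are close copies whose probe sets were not told apart here. Cbln1, a synaptic organiser, rose 24.9-fold (log2 4.64, SE 0.158). The neuropeptide precursors Nts and Npy rose 22.9-fold and 9.12-fold, and the calmodulin regulator Pcp4 rose 12.7-fold. Clu, an extracellular chaperone, rose 19.5-fold from 6.53 to 10.82. The transcription factor genes Plagl1, Ehf and Dlx5 rose by 3.91, 3.64 and 3.40 on the log2 scale. Adjusted p-values of these 11 genes lay between 1.91e-08 (Krt6a) and 1.4e-06 (Krt6b).

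The 12 largest falls held 6 genes of matrix proteins or a matrix protease, namely Aspn, Ogn, Dcn, Spon2, Adamts5 and Mgp. After Aspn, the proteoglycan genes Ogn and Dcn were 22.4-fold and 13.0-fold lower (log2 -4.49, SE 0.138, and log2 -3.70, SE 0.158). The growth factor binding protein gene Igfbp5 was 17.5-fold lower (log2 -4.13, SE 0.178), and the carbonic anhydrase gene Car3 14.8-fold lower (log2 -3.89, SE 0.17). Ptn, a secreted growth factor, was 9.94-fold lower. Enpp3, Spon2, Cd200, Dhrs3, Adamts5 and Mgp were 9.72-fold, 8.94-fold, 8.9-fold, 8.64-fold, 8.42-fold and 8.16-fold lower. Adjusted p-values of these 11 genes lay between 4.15e-08 (Ogn) and 9.28e-07 (Mgp).

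**Figure D2:**
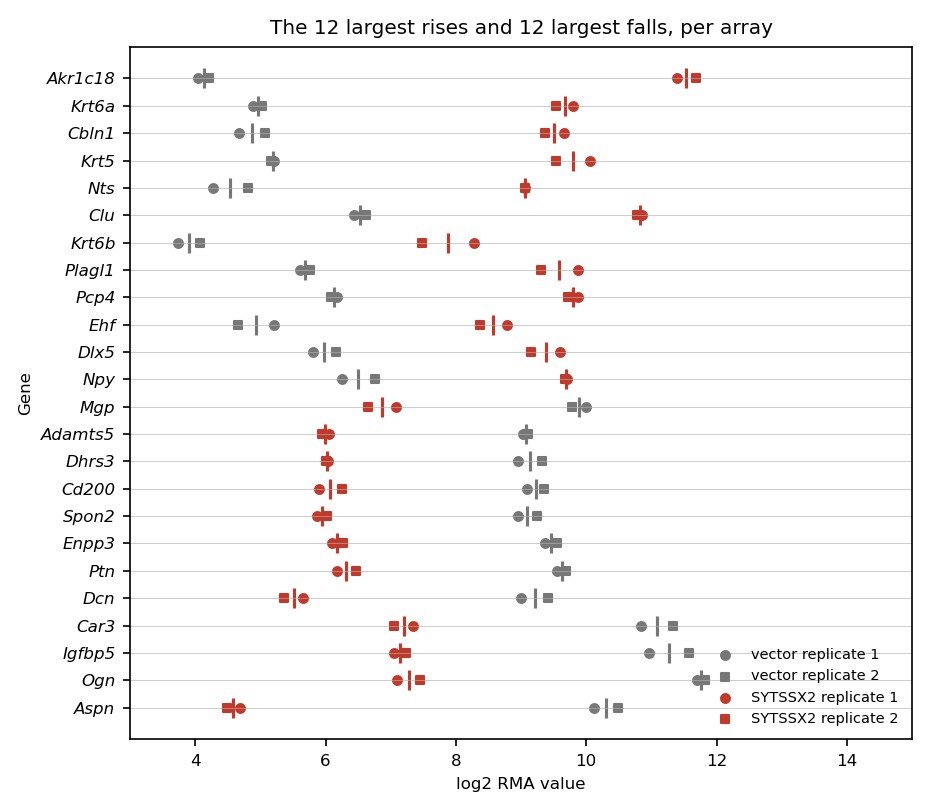
Log2 RMA value per array (x axis) of the 12 genes with the largest rise and the 12 with the largest fall (y axis). Grey symbols are vector arrays and red symbols fusion arrays, circles replicate 1 and squares replicate 2, and the vertical tick is the mean of 2 arrays. Akr1c18 has the widest gap, from a mean of 4.13 to 11.54.

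Genes were then grouped in 42 lists. With camera and its preset correlation of 0.01, 22 lists passed at an adjusted p under 0.05, 14 of them higher and 8 lower in the fusion arrays. With a correlation estimated from these 4 arrays, camera called 0 lists (adjusted p from 0.464 to 0.941, and 3 lists at an unadjusted p under 0.05), and fry, which asks whether a list moves one way on balance, called 6. The 6 were the fibrillar collagen, smooth muscle, neurotrophin, Polycomb, inflammatory and metalloproteinase lists. The estimated value is given beside each list that camera called. Camera then has only the 2 residual degrees of freedom, so these p-values alone do not show that correlation between genes removes a call.

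Camera called the matrix and smooth muscle lists lower with the preset correlation, and 0 of these 2 with an estimated one. Of 35 fibrillar collagen and matrix genes, 22 fell and 1 rose, with the same numbers adjusted over the list alone, and their median log2 difference was -0.87 (camera adjusted p = 8.04e-15, 0.464 with an estimated correlation). Besides Dcn, the list held Postn, 7.57-fold lower, Col3a1, 6.5-fold lower, and Col5a2, 4.5-fold lower. Of 17 smooth muscle genes, 9 fell (10 lower and 1 higher adjusted over the list alone), among them Actg2, 4.61-fold lower, Mylk, 3.44-fold lower, and Acta2, 2.06-fold lower. Their median was -0.63, or -0.39 without fusion replicate 2, and camera gave an adjusted p of 8.4e-06, or 0.464 with an estimated correlation.

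Camera called 3 skeletal muscle lists lower with the preset correlation, and 0 of them with an estimated one. Of 46 contractile and sarcomere genes, 14 fell and the other 32 did not pass (15 lower adjusted over the list alone), with Actn3 2.85-fold, Des 2.48-fold and Actc1 2.25-fold lower. Of 30 muscle metabolism, receptor and fusion genes, 11 fell and the other 19 did not pass (12 lower adjusted over the list alone). Chrna1, Chrng and Chrnd, subunits of the acetylcholine receptor, were 6.58-fold, 2.61-fold and 2.54-fold lower, and the ubiquitin ligase gene Fbxo32 2.7-fold lower. The median log2 differences of these lists were -0.17 and -0.22, with camera adjusted p-values of 3.31e-05 and 8.4e-06, or 0.496 and 0.464 with an estimated correlation. Of 23 myogenic transcription factors, 7 fell and 3 rose (8 and 3 adjusted over the list alone), at a median of -0.17 and a camera adjusted p of 0.0155, or 0.496 with an estimated correlation. The myogenic factor genes Myod1 and Myog were 2.57-fold lower (log2 -1.36, SE 0.16) and 2.97-fold lower (log2 -1.57, SE 0.178). Myf5 was 1.51-fold lower, with an adjusted p of 0.00737 that became 0.059 without fusion replicate 2. Pax7, of the satellite cell, had a log2 difference of 0.04 (adjusted p = 0.879). Vector replicate 2 had the higher muscle gene levels of the 2 vector arrays: 19 of 76 contractile and other muscle genes were higher in vector replicate 1. Without vector replicate 2 the medians of the contractile, other muscle and myogenic factor lists were -0.07, -0.14 and -0.13. With the preset correlation camera then still called the contractile and other muscle lists lower, but not the myogenic factor list. Without vector replicate 1 the contractile median was -0.32.

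Camera called 3 neural lists higher with the preset correlation, and 0 of them with an estimated one. Of 68 transcription factors of neural development, 12 rose and 1 fell (13 and 1 adjusted over the list alone), at a median of 0.15. Besides Dlx5, 10.5-fold higher, Zic2 rose 3.51-fold, Olig2 2.55-fold and Pou3f1 2.38-fold. Sox2 rose 1.44-fold from 5.34, within the background range, with an adjusted p of 0.0109 that was 0.0504 and 0.052 without fusion replicate 1 and fusion replicate 2. Of 42 neuronal cytoskeleton, synapse and secretion genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone), at a median of 0.08. The neurofilament gene Nefm rose 5.96-fold, Tubb3, the neuronal tubulin, 5.42-fold and Cntn2 2.99-fold, whereas the adhesion molecule gene Ncam1 was 2.29-fold lower. Of 19 neurotrophin and glial factor signalling genes, 7 rose and 1 fell (8 and 2 adjusted over the list alone), at a median of 0.11. The receptor genes Ngfr, Ret and Cntfr rose 5.87-fold, 4.65-fold and 3.19-fold. Camera gave adjusted p-values of 3.31e-05, 0.00313 and 0.0024 for these 3 lists, or 0.496, 0.496 and 0.464 with an estimated correlation. Without vector replicate 2 their medians were 0.23, 0.17 and 0.20. The first was 0.09 without vector replicate 1, and the second 0.06 without fusion replicate 1 and 0.14 without fusion replicate 2. Axon guidance genes moved both ways: of 51, 11 rose and 13 fell (14 and 17 adjusted over the list alone), and the list was not called (camera adjusted p = 0.206). Efna3 rose 4.43-fold, while Sema3e, Sema3a, Ephb6 and Ephb3 were 5.39-fold, 5.31-fold, 3.93-fold and 2.1-fold lower. Efnb1 was 1.5-fold higher, with an adjusted p of 0.041 that became 0.27 without fusion replicate 1 and 0.112 without vector replicate 1. Ephb4 had a log2 difference of -0.13 (adjusted p = 0.621). Of 24 neural crest genes, 6 rose and 5 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.273). In this list Id4 rose 4.27-fold, Id2 4.07-fold and the receptor gene Kit 2.77-fold, and Snai2 was 3.97-fold lower.

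**Figure D3:**
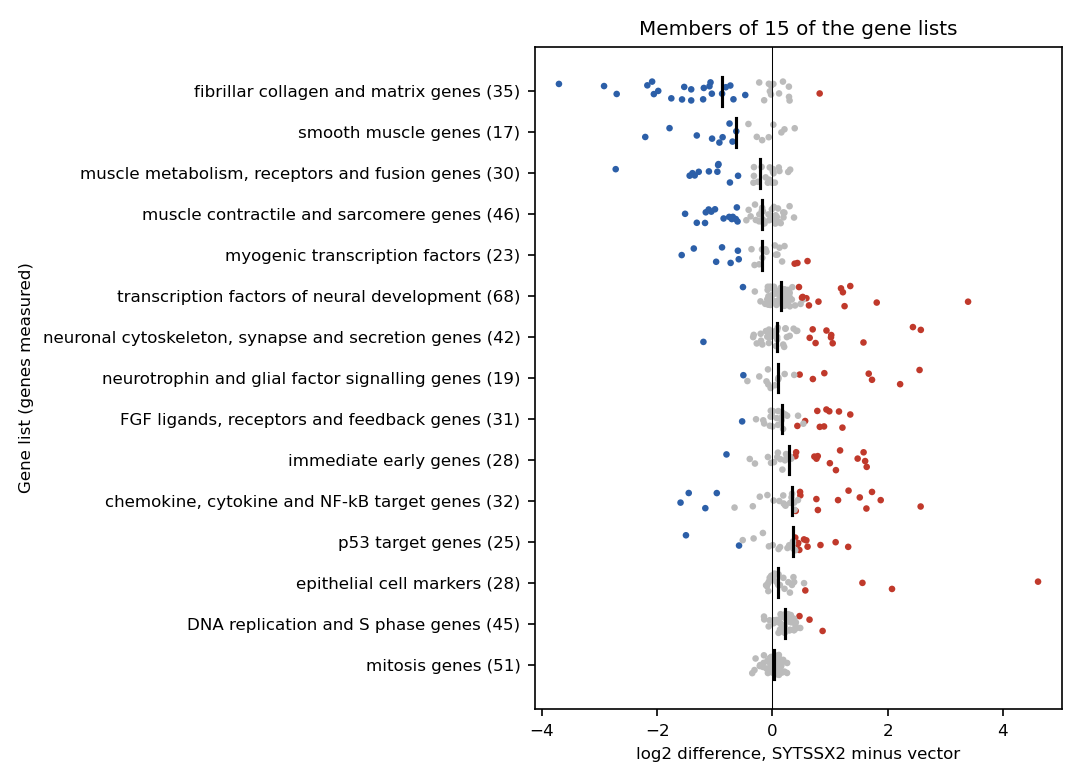
Log2 difference, fusion minus vector (x axis), of each measured member of 15 of the 42 gene lists (y axis, with the number measured). Each point is a gene, red if it rose, blue if it fell and grey if it did not pass, and the black bar is the list's median. The bar of the fibrillar collagen and matrix genes stands at -0.87 and that of the mitosis genes at 0.03.

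Among signalling pathways, the FGF list was called higher and the IGF axis list lower. Of 31 FGF ligands, receptors and feedback genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone), at a median of 0.17 and a camera adjusted p of 0.000293, or 0.464 with an estimated correlation. Their median was 0.07 without vector replicate 1 and 0.29 without vector replicate 2. Fgf9 rose 2.55-fold, and the feedback and target genes Dusp6, Etv4 and Dusp5 rose 2.32-fold, 2.23-fold and 1.98-fold. Fgfr2 did not pass, with a log2 difference of 0.446 (adjusted p = 0.0821). The difference was 0.601 and 0.607 without vector replicate 2 and fusion replicate 2 (adjusted p = 0.0164 and 0.0371), and 0.292 and 0.285 without vector replicate 1 and fusion replicate 1 (adjusted p = 0.294 and 0.418). Of 16 IGF axis genes, 7 fell and 2 rose, the same adjusted over the list alone, at a median of -0.09 and a camera adjusted p of 0.0155, or 0.496 with an estimated correlation and 0.0622 without vector replicate 2. The median was -0.22 without vector replicate 1, -0.17 without fusion replicate 1 and -0.06 without fusion replicate 2. Igfbp7 was 3.15-fold lower beside Igfbp5, whereas Irs2 rose 2.44-fold. The growth factor gene Igf2 rose 2.54-fold from 7.60 ± 0.674 to 8.94 (n = 2 each, log2 1.34, SE 0.243), a log2 difference that was 0.87 without vector replicate 1. Wnt genes moved both ways, with 9 of 53 higher and 5 lower (10 and 6 adjusted over the list alone, camera adjusted p = 0.368). The receptor gene Lgr5 rose 5.62-fold, the ligand genes Wnt7b and Wnt7a 3.51-fold and 2.12-fold, and the target gene Axin2 1.99-fold. Of 15 Hedgehog pathway genes, 3 rose and 4 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.342). Ptch1, receptor and target of the pathway, rose 3.31-fold and Gli2 1.84-fold, while the co-receptor genes Gas1 and Boc were 2.33-fold and 1.61-fold lower. Gli1 and Hhip did not pass limma's test, with log2 differences of 0.219 and -0.344 (adjusted p = 0.299 and 0.26). Of 28 Notch pathway genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.211), with Hes1 2.19-fold and Nrarp 2.07-fold higher and Maml3 1.82-fold lower. TGF-beta and BMP pathway genes had 8 of 44 higher and 7 lower (8 and 8 adjusted over the list alone, camera adjusted p = 0.675), with Tgfbr1 2.39-fold higher and Tgfbr2 2.12-fold lower.

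Developmental regulators and chromatin genes changed in part. Of 72 other developmental transcription factors often marked by Polycomb, 10 rose and 2 fell (11 and 3 adjusted over the list alone), at a median of 0.12. Foxd1 rose 5.38-fold, Foxf1 4.79-fold (log2 2.26, and 3.355 by its second probe set) and Foxc2 2.33-fold, and Foxc1 was 2.68-fold lower. The list's camera adjusted p was 0.0047, or 0.496 with an estimated correlation and 0.0502 without vector replicate 1, where its median was 0.07. Of 37 Hox cluster genes, 4 rose and 2 fell, the same adjusted over the list alone. Hoxb9 rose 5.1-fold, Hoxb6 2.27-fold and Hoxb13 1.62-fold, and Hoxc10 was 1.81-fold lower. The Hox list was not called, with a camera adjusted p of 0.342, which was 0.0444 without vector replicate 2 and 0.997 without vector replicate 1. Of 31 Polycomb complex genes, 3 rose and the other 28 did not pass, the same adjusted over the list alone, at a median of 0.11. The 3 were Rybp, 3.16-fold, Bcor, 1.58-fold, and Pcgf6, 1.51-fold, all of variant Polycomb repressive complexes, and the second Rybp probe set had a log2 difference of 0.48 against 1.66. Ezh2 and Bmi1 did not pass, with log2 differences of 0.27 (adjusted p = 0.163) and -0.29 (adjusted p = 0.159). Camera gave the Polycomb list an adjusted p of 0.0279, or 0.496 with an estimated correlation and 0.0759 without vector replicate 2. Of 30 SWI/SNF complex genes, 4 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.273), and Smarcd3, the member that fell, was 1.82-fold lower. Of 27 genes used as markers of synovial sarcoma, 5 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.149, or 0.0445 without vector replicate 2 and 0.315 without vector replicate 1). Tle4 rose 5.73-fold and Cxcr4 2.42-fold, and Egfr was 2.69-fold lower, while Tle1 and Bcl2 had log2 differences of 0.24 (adjusted p = 0.218) and 0.14 (adjusted p = 0.526).

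Markers of other lineages and cell types moved with the groups in a few cases. Of 28 epithelial cell markers, 4 rose and the other 24 did not pass, the same adjusted over the list alone. The 4 were the keratin genes Krt5, Krt14, 4.22-fold, Krt17, 2.96-fold, and Krt19, 1.49-fold, whose adjusted p of 0.0156 became 0.124 without fusion replicate 2. Cdh1, E-cadherin, had a log2 difference of -0.11 (adjusted p = 0.645). The list had a median of 0.11 and a camera adjusted p of 0.0026, or 0.496 with an estimated correlation, and its median was 0.07 without vector replicate 1. Of 19 endothelial cell markers, 2 rose and the other 17 did not pass, the same adjusted over the list alone: Kdr, 2.03-fold, and Flt4, 1.53-fold with an adjusted p of 0.0124, or 0.107 without fusion replicate 1. The endothelial list had a median of 0.17 and a camera adjusted p of 0.0272, which was 0.496 with an estimated correlation, 0.252 without vector replicate 1, where the median was 0.08, and 0.0526 without fusion replicate 1. Of 24 macrophage and leukocyte markers, Laptm5 rose 4.28-fold and Cd53 was 1.86-fold lower, the only 2 that passed, also adjusted over the list alone (camera adjusted p = 0.614). Of 25 cartilage and bone genes, 5 rose and 1 fell, the same adjusted over the list alone. Alpl rose 2.67-fold, Sox9 2.26-fold and Acan 2.22-fold, and Phex was 2.49-fold lower, with a camera adjusted p of 0.149 for the list, or 0.0235 without vector replicate 2 and 0.47 without vector replicate 1. Of 21 adipocyte genes, 2 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.273), and Lpl was 2.17-fold lower.

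Of the lists of genes that respond to growth factors, inflammation and stress, camera called 4 higher and 1 lower with the preset correlation, and 0 with an estimated one. Of 28 immediate early genes, 12 rose and 1 fell (13 and 2 adjusted over the list alone), at a median of 0.28, with Ier3 3.11-fold, Dusp1 3.05-fold, Atf3 3-fold and Maff 2.79-fold higher. Of 32 chemokine, cytokine and NF-kB target genes, 12 rose and 4 fell (17 and 6 adjusted over the list alone), at a median of 0.34. Ccl2 rose 5.95-fold, Cxcl1 3.68-fold, Lif 3.31-fold and Il33 3.1-fold. Of 25 p53 target genes, 10 rose and 2 fell (13 and 3 adjusted over the list alone), at a median of 0.36, with Btg2 2.49-fold and Gadd45b 2.14-fold higher and Sesn1 2.83-fold lower. Camera gave these 3 lists adjusted p-values of 8.4e-06, 0.000284 and 0.00214, or 0.496, 0.464 and 0.496 with an estimated correlation. Of 20 heat shock genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone), at a median of 0.24 and a camera adjusted p of 0.00259, or 0.496 with an estimated correlation and 0.0622 without vector replicate 2. Its median was 0.15 without fusion replicate 1. The small heat shock protein genes went opposite ways, Hspb1 2.97-fold higher and Cryab 2.26-fold lower. Interferon-stimulated genes were called lower: of 41, 9 fell and 2 rose (10 and 2 adjusted over the list alone), at a median of -0.04. Ifit1, Ifi27, Ifitm3 and Ddx58 were 3.65-fold, 2.33-fold, 2.21-fold and 1.86-fold lower, with a camera adjusted p of 0.0257 for the list, or 0.496 with an estimated correlation and 0.11 without fusion replicate 1. The list's median turned to 0.015 in that case, and was -0.10 without vector replicate 2 and -0.16 without fusion replicate 2. Of 33 genes of the unfolded protein response and amino acid stress, 6 rose and 4 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.517).

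Of the D cyclin genes, Ccnd1 and Ccnd2 rose and Ccnd3 had a log2 difference of 0.05 (adjusted p = 0.848). Of 16 cyclin D and CDK inhibitor genes, 5 rose and 3 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.264). Ccnd2 rose 7.56-fold, Cdkn1c 2.45-fold, Myc 1.95-fold and Ccnd1 1.69-fold, and Cdkn2a had a log2 difference of 0.19 (adjusted p = 0.412). Of 45 DNA replication and S phase genes, 3 rose (10 adjusted over the list alone), at a median of 0.22 and a camera adjusted p of 1.1e-05, or 0.527 with an estimated correlation. Orc1 rose 1.83-fold (log2 0.87, and 0.57 without vector replicate 2). By limma, 0 of 51 mitosis genes passed over all genes or adjusted over the list alone, with 1 higher and 3 lower at an unadjusted p under 0.05, and the list was not called (camera adjusted p = 0.746). In the same way 0 of 18 histone genes passed, with 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.273), also adjusted over the list alone. Of 37 cytosolic ribosomal protein genes, 0 passed by limma over all genes or adjusted over the list alone, with 6 higher at an unadjusted p under 0.05. Their median of 0.15 had a camera adjusted p of 0.00214, or 0.553 with an estimated correlation, 0.0843 without vector replicate 2 and 0.081 without fusion replicate 2.

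Metabolic and adhesion genes made up the remaining lists. Of 24 sterol synthesis genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone), at a median of -0.21, with the desaturase genes Scd1 and Scd2 1.7-fold and 1.59-fold lower. The list's camera adjusted p was 0.00561, or 0.553 with an estimated correlation, 0.172 without fusion replicate 1 and 0.158 without vector replicate 1. Its median was -0.11 without vector replicate 1 and -0.32 without vector replicate 2. Of 29 glycolysis and hypoxia genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.308). Ndrg1 rose 3.89-fold, and P4ha2 and Pdk1 were 2.44-fold and 1.91-fold lower. Of 44 genes of the mitochondrial respiratory chain, 1 fell, Cox6a1, and 0 passed by limma adjusted over the list alone, with 2 higher and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.308). Cox6a1 was 1.32-fold lower with an adjusted p of 0.0494, which became 0.149, 0.186 and 0.186 without fusion replicate 1, fusion replicate 2 and vector replicate 1. Of 24 metalloproteinase and inhibitor genes, 6 rose and 8 fell (7 and 9 adjusted over the list alone, camera adjusted p = 0.28). The inhibitor gene Timp3 rose 5.13-fold and Mmp9 3.15-fold, and Mmp19 was 3.27-fold lower beside Adamts5. Of 35 cell adhesion and EMT genes, 2 rose and 9 fell (5 and 10 adjusted over the list alone, camera adjusted p = 0.174), with Cdh11 3.56-fold lower and Itga6 2.01-fold higher. Actb, beta-actin, had a log2 difference of -0.23 (adjusted p = 0.288).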

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

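Signals outside the comparison of named genes were looked for in the probe sets that the platform table pairs with no gene or with several. With all 35557 probe sets in the fit, 41 of the 12147 unnamed probe sets rose at least 2-fold over the vector arrays at an adjusted p under 0.05, and 37 fell. The 41 hold 36 different sets of values, since some probe sets repeat another's. The largest change among the unnamed was in probe set 10358339, which was lower by 3.49 on the log2 scale (log2 -3.49, SE 0.233, adjusted p = 0.00614), and the next in probe set 10368289 (log2 -3.13, SE 0.143). Of the 1621 probe sets shared by several genes, 7 rose at least 2-fold and 5 fell. Probe set 10559978 went from 5.16 in the vector arrays to 9.13 in the fusion arrays (n = 2 each, log2 3.97, SE 0.511, adjusted p = 0.0277). What these probe sets read, and whether some are controls of the array and not transcripts, was not analysed here.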

How the results depend on the processing

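All alternatives below were chosen before the data were examined. No named gene that was called changed sign, which with an array left out follows from groups that do not overlap. No called list changed camera's direction, but the median of the interferon list, -0.04, was 0.015 without fusion replicate 1. Of the 164 named genes that were called, 121 kept direction and call under every alternative in which they were tested, and of the 23 not called, 8 passed in at least 1. The filters on dim genes removed some named genes, and other thresholds were applied to the counts only. The count of changed genes was 2522, and stayed within 1.5 times of that under both filters on dim genes, the mean of probe sets, a variance trend, robust estimation, 3 further normalizations, the replicate block and each array left out. It fell to 1370 at an adjusted p under 0.01. With all probe sets in the fit, 1098 probe sets passed, 193 of them with no or several genes, and of the 2522 genes 826 passed by the probe set used here, with prior degrees of freedom of 3.19 against 8.31. At least 2-fold changes numbered 585, and 1471 and 196 at a 1.5-fold and a 3-fold minimum, as those limits imply. The 22 lists called became 0 with an estimated correlation and 6 with fry, which asks another question. The estimated correlation of the smooth muscle, neurotrophin, Polycomb and inflammatory lists was 0.006, -0.009, -0.022 and -0.016, under the preset 0.01. A higher correlation between genes therefore did not remove the call of these lists. With an estimated correlation camera has only the 2 residual degrees of freedom. In the other called lists the estimate lay above the preset, from 0.017 (FGF) to 0.524 (sterol synthesis). It was 0.509 for the DNA replication and S phase list and 0.451 for the ribosomal protein list. The preset p-values of these other lists therefore assume less correlation than was estimated. Whether correlation removed their calls was not tested. Of the 22, 12 kept their call under the remaining alternatives in which they were tested, and 4 uncalled lists passed in at least 1. With each array left out in turn, 1701 to 2520 genes, 543 to 643 genes at least 2-fold, and 19 to 21 lists passed, and 0 to 0 of the Ss18 and Ssx probe sets. Centring each array on its median gave 40.3% of calls higher against 47.9%, and moved the median of all genes to -0.032 (log2). The medians of the mitosis and Wnt lists, which were not called, then changed sign, to -0.003 and -0.008.

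With the replicate number as a block, 3045 genes, 585 genes at least 2-fold and 22 lists passed. Same-numbered arrays deviated from their group means with a correlation of 0.0825 across genes. With 2 pairs this does not show that the numbers pair the samples, which share only a number. The number of arrays limits precision in either case. Signal over background could be judged only from the olfactory receptors, whose 95th percentile lay above the vector mean of 6362 tested genes.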

Other observations

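The tests on keratin and muscle genes were chosen only after the result was seen, as were the genes and families singled out in the next paragraph. Families were formed by symbol stem, and 233 with at least 10 tested genes were compared with all tested genes in each direction by one-sided Fisher's exact test, adjusted over 466 tests, of which 10 passed. The test takes genes as independent, which members of a family are not. All tested genes include those at background, such as 1027 olfactory receptors, of which 4 rose and 6 fell, and this lowers the number expected. The family counts given below moved by at most 1 gene under each of the 3 further normalizations, but the Fisher tests were not repeated on them. With each array centred on its median, for example, 6 Dusp and 6 Polr genes rose, against 7 and 7. Whether the adjusted p-values of these families stay under 0.05 there is not known.

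Protocadherin genes of the beta cluster, which encode neuronal adhesion proteins, were lower: 9 of 22 fell (adjusted p = 0.00121), with Pcdhb16, Pcdhb22 and Pcdhb21 at log2 differences of -1.57, -1.56 and -1.55. These genes are close copies of each other, and their probe sets were not told apart here. Of 16 carbonic anhydrase genes, 6 fell and 2 rose (adjusted p = 0.0237 for falls), with Car2 at -2.73 and Car5b at -2.17 beside Car3. Of 20 semaphorin genes, 7 fell and 2 rose (adjusted p = 0.015 for falls), and of 18 Adamts protease genes, 7 fell (adjusted p = 0.00931). Of 44 collagen genes, 11 fell and 4 rose (adjusted p = 0.00931 for falls), and the basement membrane genes Col4a1 and Col4a2 rose by 0.83 and 1.26 on the log2 scale. Tbc family genes, which include Rab regulators, fell in 8 of 30 cases and rose in 4 (adjusted p = 0.0287 for falls). Of 10 Utp genes, which encode parts of the small subunit processome, 6 rose (adjusted p = 0.00128), with Utp18 at 0.78. Of 27 Polr genes, of the nuclear RNA polymerases, 7 rose and 1 fell (adjusted p = 0.0415 for rises), with Polr1e at 0.70 and Polr3g at 0.86. Dusp phosphatase genes rose in 7 of 24 (adjusted p = 0.0237), and 2 fell.

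Neuropeptide precursors and imprinted genes were tested as hypotheses, with the expected outcome written down first. Of 47 neuropeptide and peptide hormone precursors measured, 13 rose and the other 34 did not pass. Besides Nts and Npy, Pyy and Pnoc rose 6.09-fold and 5.99-fold, Cck 4.27-fold, Tac1 3.71-fold and Sst 2.71-fold. With the 5 precursors first noticed left out, 8 of the remaining 42 rose, against 6.05% of all tested genes (one-sided exact binomial p = 0.00333, genes taken as independent, which they are not). Of the 8, Tac1, Vip, Gcg, Pdyn and Gal had vector means from 4.01 to 5.48. These lie under the olfactory receptors' 95th percentile of 5.52, so that their folds depend on the background. Sst, Nppc and Edn1 lay above it. For the same 42, camera gave p = 0.00031 with the preset correlation and 0.179 with an estimated one, so that support for a rise of the class depends on that setting. The second test also has only the 2 residual degrees of freedom, so it cannot show whether correlation between the genes is the reason. Since Plagl1 is known to act on other imprinted genes, these may move with it. Of 35 imprinted genes measured, 7 rose and 5 fell (7 and 8 with each array centred on its median), among them Phlda2, 4.09-fold higher, Peg10, 2.96-fold higher, and Peg3, 4.49-fold lower. Without Plagl1 the remaining 34 leaned lower, with a camera p of 0.663, and called members moved apart by more than their errors, which argues against a common rise.

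Among symbol families the keratins had the lowest p for rises: 15 of 52 genes rose where 3.15 were expected, and 1 fell (one-sided Fisher's exact test, adjusted p = 0.000123 for rises). Epithelial cells in the fusion cultures would bring their other abundant transcripts, yet 27 keratinocyte genes other than keratins had a median log2 difference of 0.018 (quartiles -0.066 to 0.169), and only Cldn1, Ly6d and Gjb2 rose. Signal of a type II keratin in the probe sets of its copies cannot be the whole cause, since the type I keratins Krt14 and Krt17 rose by a mean of 1.82. Of the other type I keratins, Krt19 and Krt24 rose, Krt13 fell and the rest did not pass. It stays open for the type II genes, taken as the keratins on the chromosome of Krt5 without Krt18. Of the 21 measured other than Krt5, Krt6a and Krt6b, 8 rose, among them Krt90, 6.24-fold, and Krt75, 6.5-fold. Without probe sequences shared signal and separate rises cannot be told apart. Shared signal among type I keratins and a response of the myoblasts to the fusion protein were not tested and stay open.

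By their median, muscle genes fell by little in one same-numbered pair of arrays and by more in the other. The 76 contractile and other muscle genes had medians of -0.098 in pair 1 and -0.326 in pair 2 (log2), and 41 of 76 were lower in both. These medians include genes in the background range, such as Myh4 and Neb, with vector means of 4.99 and 5.16. The 4 called members of each list with the largest falls fell in both pairs, given here as pair 1, pair 2. Chrna1 fell alike (-2.71, -2.72). Des (-1.36, -1.26), Actn3 (-1.56, -1.47), Chrnd (-1.53, -1.165) and Chrng (-1.53, -1.24) fell more in pair 1. Fbxo32 (-1.28, -1.59), Tnnt1 (-0.883, -1.427) and Actc1 (-0.785, -1.551) fell more in pair 2. That vector replicate 2 was the only source is argued against by single genes: without it, limma called 24 of the 76 lower and 0 higher, against 25 and 0 with it, though vector replicate 1 is then a lone array. This count took the place of the list test below after both were seen. That list test, by camera, does not settle the matter, since its call of the contractile list depended on the correlation setting with and without that array. Without vector replicate 2 the contractile median went from -0.171 to -0.074. More differentiated cells in that array stay open as part of the cause. The 76 genes had a median of 0.164 for vector replicate 2 over vector replicate 1, but -0.098, the smaller fall, rests on 1 array per group and cannot be told apart from the bound of -0.1 set for this test. Fewer cells outside the cell cycle in the fusion cultures might be another part. The mitosis list had a median of 0.034, with -0.068 and 0.137 in the same-numbered pairs. DNA replication and S phase genes were higher in both pairs, by medians of 0.165 and 0.303. Their median was 0.223, and 0.151 without vector replicate 2. The bound first set for the mitosis test was widened to its genes' median SE of 0.118 after the value was seen. That SE is of single genes, and how far a small share of such cells would move the median was not measured. The explanation stays open, as does a direct effect of the fusion protein, which was not tested.

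Neighbouring genes rose together more often than permuted labels gave. With genes ordered along the chromosomes, 92 adjacent pairs of different symbol families, not overlapping, both rose, against a mean of 67.6 and a highest of 99 in 10000 permutations within 10 bins of the mean level (one-sided permutation p = 0.001). Copies with the same symbol stem are left out of this count, which argues against them as the whole cause. Relatives under other stems stay in it, such as Krt75 with Gm5414, Kit with Kdr and Cx3cl1 with Ccl17, and for such pairs shared sequence was not tested. For falls the count was 135 against 82.1 (p = 1e-04, the smallest these permutations can give). Examples of rises are Slc22a23 with Pxdc1 (log2 2.20 and 1.84), Sdc3 with Laptm5 (1.65 and 2.10) and Irf8 with Foxf1 (0.73 and 2.26). Change along chromosome domains is a candidate explanation for both directions, and pairs that share a promoter or a function were not separated from it.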
